A study of Mus musculus with 2 samples.

How the data were processed

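RNA bound to ribosomes of Drd2-expressing cells was measured on arrays. The mice carried a Cre driver for Drd2 together with RiboTag, an allele that lets Cre-expressing cells incorporate a haemagglutinin-tagged ribosomal protein (Rpl22), so that ribosomes of those cells, with the messengers on them, can be pulled down from a tissue lysate with an antibody to the tag. Per the labels' protocols, medial prefrontal cortices were pooled, RNA was taken from the precipitated ribosomes with Trizol and a purification column, and it was labelled with biotin using the Affymetrix WT Plus kit for whole-transcript arrays. The labels describe 2 samples, each as a technical replicate of a pool of 5 adult mice. They are taken to share 1 pool, which the labels do not say outright. Both belong to 1 group, whose cells the labels call neurons, and no unprecipitated RNA, mock precipitation or second condition was analysed here.

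The deposited table holds 1 value per probe set and array on what the values show to be a log2 scale. The log base, the background correction, the summarisation method and the normalization are not given in the sources used here. The columns have nearly equal quartiles (4.50, 5.80 and 7.79 on replicate 1 and 4.52, 5.81 and 7.79 on replicate 2), and whether the authors normalized the arrays together is not given in those sources. Each of the 34472 probe sets has a value on both arrays, and 0 columns of per-sample values were left unused. Scanner files were not used here, so no detection p-value or control-probe background was at hand.

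Probe sets were named from the platform annotation. Of the 34472 probe sets, 23521 named 1 gene, 1814 named several genes and were not used to name any, and 9137 are unnamed here. Symbols were checked through their gene identifiers against a RefSeq gene table of the assembly GRCm38.p6, which changed 0 of them. Probe sets of a gene were averaged, which gave 22180 named genes, 1082 of them with more than 1 probe set. In 467 of these 1082 genes the probe sets lay on different sides of the background threshold described next. Calls and list counts rest on the mean of a gene's probe sets, so a gene whose mean is not above a threshold can still have a probe set that is. Likewise, a gene whose mean is above a threshold can have a probe set that is not. Ctgf was found under its synonym Ccn2, and mitochondrially encoded genes under their RefSeq symbols, a match made after the table's names were seen. List members without a probe set of their own were not analysed here. Gene positions are not given, because the sources used here name no genome build for the array values.

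The design has no control sample, so background was set within each array. A gene was called above background where its log2 signal exceeded, on both arrays, the 95th percentile of 1394 olfactory and vomeronasal receptor genes. Threshold, gene lists and the rule for named genes were fixed before the data were examined. For each of 33 gene lists, the number of measured members above background was counted, and the list's median log2 signal was placed among the medians of 10000 random lists of the same size drawn from all named genes. This percentile describes these arrays and is not a test. Because all named genes include those not above background, lists of genes above background tend to rank high. Probe sets bind their targets with different strength, so the level of a single gene was not ranked against that of another gene. Named genes were Drd2 and the other dopamine receptors, the first 4 measured members of each list in its written order, any member on the other side of the threshold from most of its list, and the 10 genes above background with the largest absolute difference between the arrays. Other list members are named in places, and these were chosen after their values were seen.

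No p-value is given. The arrays are technical replicates of a pool, so their spread measures labelling, hybridisation and any earlier step repeated between them, and not the variation between animals. Values are means ± SD over the 2 technical arrays. The number of arrays limits the precision of every value. The alternatives planned were the 99th percentile of the sensory receptor genes, the 95th percentile of the testis, liver and skeletal muscle lists (the out-of-tissue threshold), the median of all probe sets, the highest probe set of a gene, only genes with 1 probe set, quantile normalization and each array alone. Random lists drawn from the genes above background, lists without members shared with another list, and the gene families of the closing section were added after the data were seen. The procedure was tested on simulated data for 22180 genes: a technical SD of 0.2 was recovered as 0.200, and 100.0% of 200 genes set 1 log2 unit above the threshold and 0.0% of 200 genes set 1 unit below it were called. Of 200 unchanged random lists of 10 genes, 5.0% passed the 95th percentile of random lists, against 95.5% of lists raised by 3 log2 units. The 5.0% follows from the definition of the percentile. The simulated genes lay far from the threshold for that SD, which was the same at every signal. Calls close to the threshold were therefore not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and figures were drawn with matplotlib 3.10.9.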

Results

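Ribosome-bound RNA of Drd2-expressing cells from the medial prefrontal cortex of adult mice was profiled on 2 arrays, labelled as technical replicates of a pool of 5 animals and taken to share that pool. Drd2 encodes the dopamine D2 receptor. The samples form 1 group, so the data describe which genes gave signal in this RNA and how well the arrays repeated each other. They hold no measure of enrichment over whole cortex, since no unprecipitated RNA was analysed here. No mock precipitation was analysed either, so signal of a marker does not show that the captured cells express it. All values are log2 signals, a scale inferred from their range, given as the mean ± SD over the 2 technical arrays (n = 2 arrays of a pool, no biological replicates).

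The arrays gave nearly the same profile. Over the 34472 probe sets, signals ranged from 1.66 to 14.18 on replicate 1 and from 1.74 to 14.16 on replicate 2, with medians of 5.80 and 5.81. Across probe sets, which are not independent replicates, Pearson's r was 0.9941 and Spearman's rho 0.9918. The difference between arrays had an SD of 0.249 log2 units, and 116 probe sets (0.337%) differed by more than 1 log2 unit. Repeatability rose with signal. The SD of the difference was 0.327 for the 11673 probe sets with a mean signal under 5 and 0.100 for the 940 probe sets at 11 or more. Values carry 2 decimals, and 4.19% of probe sets had equal values on both arrays. Equal values made up 3.70% of genes above background (SD of the difference 0.149) and 4.75% of genes not above it (0.291). They were thus not rarer where the spread was larger, so rounding alone need not account for them, and their cause was not tested.

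**Figure D1:**
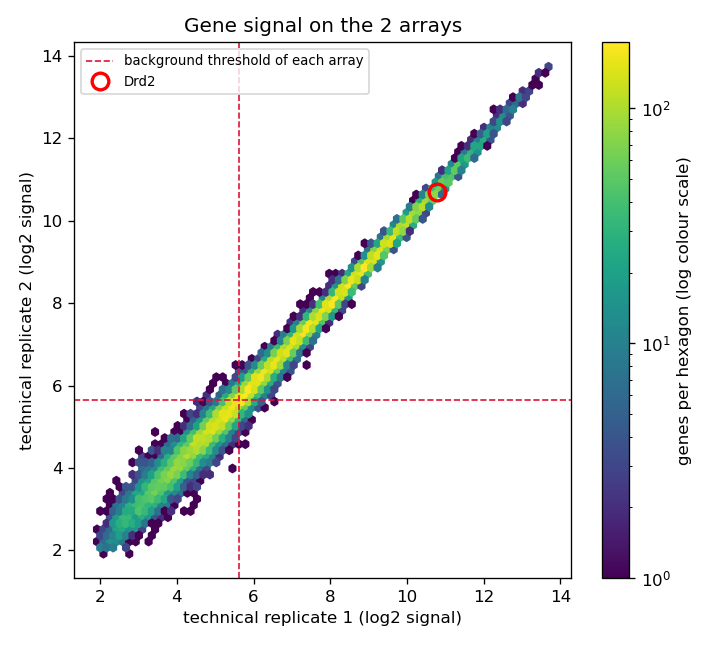
Log2 signal of each named gene on technical replicate 1 (x axis) and technical replicate 2 (y axis), coloured by the number of genes per hexagon on a log colour scale; dashed lines mark each array's background threshold and the ring marks Drd2. Genes follow the diagonal, more tightly at high signal, and Drd2 lies at 10.78 and 10.70.

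Of the 22180 named genes, 13374 (60.30%) exceeded background on both arrays, 788 on only 1 of them and 8018 on neither. Of the 20786 named genes other than the sensory receptor genes that set the threshold, 64.07% exceeded background. Background was the 95th percentile of 1394 olfactory and vomeronasal receptor genes, at 5.61 on replicate 1 and 5.66 on replicate 2. This threshold is permissive: 9 of 33 measured genes of testis, liver and skeletal muscle also passed it. The count fell to 8541 genes when the threshold was taken from those out-of-tissue genes, at 7.24 and 7.02. With 33 genes, that threshold fell between the signals of Apoa2 (7.09 and 6.67) and Odf1 (7.460 and 7.535). Odf1 itself averaged probe sets at 4.98 and 10.02, so every call at the out-of-tissue threshold hangs on few genes. Among the genes above background, 69 (0.516%) differed between arrays by more than 0.5 log2 units and 0 by more than 1. The largest difference was that of Zfp935, a zinc finger gene, at 7.38 on replicate 1 and 6.50 on replicate 2. 2700081O15Rik was higher on replicate 2 by 0.76, Trarg1 by 0.70, Mir669h by 0.68, Btbd35f2 by 0.67 and each of Cxcr1, Gm4340 and Mir467c by 0.66. Pcolce2 fell by 0.67 and Tbrg3 fell by 0.66 from replicate 1 to replicate 2. None of these 10 genes is a member of a fixed list, and only 2700081O15Rik and Mir467c passed the out-of-tissue threshold.

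The transcript that defines the captured cells gave clear signal. Drd2 stood at 10.74 ± 0.06, on average 5.10 log2 units over the background thresholds, and it stayed 3.61 units over the out-of-tissue threshold. Drd1, the main receptor of the D1 class, was also above background at 7.38 ± 0.02. It exceeded every threshold tried, but the out-of-tissue threshold by only 0.25 units on average. Drd5 was at 6.17, from probe sets at 6.83 and 5.51 that lay on different sides of the threshold. Drd4 was at 5.74 ± 0.03, on average 0.10 units over the thresholds, and Drd3 at 5.71 ± 0.15 exceeded it on replicate 2 only. Drd4 did not pass the 99th percentile of sensory receptor genes, at 6.64 on both arrays, the out-of-tissue threshold or the median of all probe sets. The Drd5 mean did not pass the 99th percentile or the out-of-tissue threshold, but its probe set at 6.83 passed the 99th percentile.

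**Figure D2:**
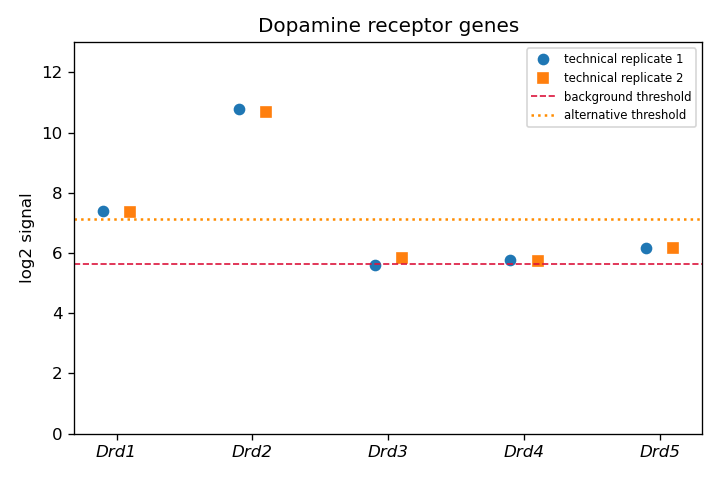
Log2 signal (y axis) of the dopamine receptor genes Drd1 to Drd5 (x axis) on technical replicate 1 (circles) and technical replicate 2 (squares), with the mean background threshold from sensory receptor genes (dashed) and that from testis, liver and muscle genes (dotted). Drd1 and Drd2 lie above both lines on both arrays, and Drd3 and Drd4 lie close to the lower line.

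With the signalling partners of the receptors, 14 of the 15 measured genes of this list were above background, Drd3 being the exception. The list's median of 10.08 exceeded those of all 10000 random lists. Members outside the receptor family, chosen after their values were seen, included the G protein subunits Gnao1 at 12.78 ± 0.01 and Gnai1 at 11.21 ± 0.02, adenylyl cyclase Adcy5 at 9.82 ± 0.07, the kinase Gsk3b at 11.84 ± 0.06 and the potassium channel subunit Kcnj6 at 8.28 ± 0.05.

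General neuronal genes and markers of cortical excitatory neurons were above background throughout. All 12 pan-neuronal genes passed, among them the synaptic proteins Snap25 at 13.70 ± 0.01 and Syt1 at 13.21 ± 0.04, the nuclear protein Rbfox3 at 11.62 ± 0.05 and the dendritic protein Map2 at 12.04 ± 0.01. All 11 measured glutamatergic markers passed, including the vesicular glutamate transporter Slc17a7 at 12.30 ± 0.03, the kinase Camk2a at 12.39 ± 0.02 and the transcription factors Neurod2 at 10.80 ± 0.08 and Neurod6 at 10.28 ± 0.02. The medians of both lists, 11.86 and 10.80, exceeded those of all 10000 random lists.

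Markers of all cortical layers examined gave signal. The 10 upper layer markers were all above background with a median of 9.08, at percentile 99.47 among random lists. They included Cux2 at 9.77 ± 0.08, Rasgrf2 at 11.10 ± 0.01 and Calb1, the calcium-binding protein calbindin, at 11.72 ± 0.03. Cux1 averaged 6.55 ± 0.04 over probe sets at 4.52 and 8.57. The 10 layer 5 markers had a median of 9.07 at percentile 99.46, with the transcription factors Fezf2 at 8.72 ± 0.04, Bcl11b at 9.41 ± 0.05 and Etv1 at 8.36 ± 0.05, and Parm1 at 10.99 ± 0.08. The 10 layer 6 markers also passed, with a median of 7.48 at percentile 84.92. Ntsr1, the neurotensin receptor of corticothalamic cells, was at 8.91 ± 0.12, Tle4 at 9.11 ± 0.01, Foxp2 at 7.05 ± 0.13 and Syt6 at 7.35 ± 0.04. Among random lists drawn only from genes above background, the layer 6 median stood at percentile 28.13, the upper layer median at 95.14 and the layer 5 median at 95.02. At the out-of-tissue threshold, 9 upper layer, 10 layer 5 and 7 layer 6 markers passed by their means. Foxp2 did not, nor did the Cux1 mean, although the Cux1 probe set at 8.57 did. Differences between these lists were not tested, since their probe sets differ.

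Inhibitory neuron genes likewise gave signal in this RNA. All 9 measured GABAergic markers exceeded background, with a median of 8.84 at percentile 98.21. Against random lists drawn only from genes above background, this median stood at percentile 88.12. By their means, all 9 also exceeded the out-of-tissue threshold. The GABA-synthesising enzymes Gad1 and Gad2 were at 8.85 ± 0.09 and 11.49 ± 0.01, the vesicular GABA transporter Slc32a1 at 8.97 ± 0.10 and the transcription factor Dlx2 at 8.52 ± 0.20. The Slc32a1 value averaged probe sets at 10.785 and 7.165, of which the latter was under the out-of-tissue threshold on replicate 2. All 14 interneuron subclass markers passed, at percentile 99.90, and 13 passed the out-of-tissue threshold. The parvalbumin gene Pvalb was at 8.22 ± 0.04, the somatostatin gene Sst at 13.71 ± 0.05, Vip at 9.53 ± 0.04 and the neuropeptide Y gene Npy at 12.07 ± 0.04. Interneuron subclass and neuropeptide lists share members, and the 6 subclass markers that stand in no other list were all above background.

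Genes typical of striatal projection neurons were above background in 8 of 9 measured cases, with a median of 8.59 at percentile 97.16. Against random lists drawn only from genes above background, this median stood at percentile 80.42. The enkephalin precursor Penk was at 12.11 ± 0.02, the orphan receptor Gpr6 at 8.90 ± 0.01, Rgs9 at 8.81 ± 0.06, the phosphodiesterase Pde10a at 9.56 ± 0.14 and the dynorphin precursor Pdyn at 8.59 ± 0.01. The transcription factor Isl1 was not above background at 5.42 ± 0.11. Of the 8 markers of dopamine-producing neurons, 4 passed, and the list's median of 5.70 stood at percentile 24.28. Tyrosine hydroxylase (Th) was at 7.05 and the dopamine transporter Slc6a3 at 5.75 ± 0.04, whereas Ddc at 5.66 ± 0.12 and the vesicular transporter Slc18a2 at 5.62 ± 0.16 did not exceed the threshold on both arrays. The other members above background were the transcription factor Nr4a2 at 9.43 ± 0.02 and the dehydrogenase Aldh1a1 at 7.76 ± 0.09, named after their values were seen, and these were the 2 that also passed the out-of-tissue threshold.

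Receptors and channels of neurons gave signal in most families. Of the 21 measured glutamate receptor genes, 19 were above background, at a median of 9.43. The AMPA receptor subunits Gria1 to Gria4 were at 11.46 ± 0.01, 12.22 ± 0.06, 11.71 ± 0.06 and 10.31 ± 0.06. Grm6, known from retina, was not above background at 4.93 ± 0.14. The mean of Grin2c, known from cerebellum, was not above it on both arrays at 5.55 ± 0.18, but its probe sets lay at 4.51 and 6.59 and the latter was above. Of the 12 measured GABA receptor genes, 11 passed, with Gabra2 at 11.11 ± 0.09, Gabra3 at 10.60 ± 0.06, Gabra4 at 10.78 ± 0.07 and Gabra5 at 10.97 ± 0.09. The cerebellar granule cell subunit Gabra6 did not, at 3.77 ± 0.05. All 16 measured voltage-gated channel genes passed with a median of 10.09, among them the sodium channels Scn1a at 10.06 ± 0.08, Scn2a at 11.37 ± 0.04, Scn3a at 9.22 ± 0.06 and Scn8a at 10.89 ± 0.01. The GABA receptor and channel medians exceeded all 10000 random lists and the glutamate receptor median stood at percentile 99.99.

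Among receptors for other modulators, 11 of 12 serotonin receptor genes were above background, at percentile 83.64. Against random lists drawn only from genes above background, the list stood at percentile 20.41. Htr1b was at 9.56 ± 0.10, Htr1a at 7.29 ± 0.18, Htr1f at 6.37 ± 0.20 and Htr1d at 5.80 ± 0.09, while Htr2b at 5.30 ± 0.09 was not above background. The 5-HT2A receptor gene Htr2a, named after its value was seen, was at 10.65 ± 0.04. Only 7 of the 12 passed the out-of-tissue threshold, which Htr1d and Htr1f did not, and the same number the 99th percentile of sensory receptor genes. Of 16 measured adrenergic, cholinergic, opioid and cannabinoid receptor genes, 15 passed, at percentile 99.78. The adrenergic receptors Adra1b and Adra2c were at 7.32 ± 0.13 and 6.81 ± 0.03, and the muscarinic receptors Chrm1 and Chrm2 at 8.96 ± 0.16 and 8.79 ± 0.04. The muscarinic receptor Chrm5, at 4.94 ± 0.11, was not above background. At the out-of-tissue threshold 11 of the 16 passed by their means, and Adra2c did not. The Chrm1 value averaged probe sets at 10.965 and 6.955, of which the latter did not pass that threshold. All 16 neuropeptide and growth factor genes were above background, at percentile 98.88, and 12 passed the out-of-tissue threshold. Against random lists drawn only from genes above background, the list stood at percentile 79.18. Of 8 measured hypothalamic neuropeptide genes 3 passed, at percentile 9.27. Oxt was at 6.42 ± 0.12, Avp at 6.76 ± 0.07 and Ghrh at 5.89 ± 0.23, and none of them exceeded the out-of-tissue threshold. Pomc at 4.75 ± 0.26 and Hcrt at 5.05 ± 0.06 were not above background.

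Markers of non-neuronal brain cells were also above background. All 10 astrocyte markers passed, with a median of 7.87 at percentile 91.78, including the intermediate filament Gfap at 6.67 ± 0.02, the water channel Aqp4 at 6.93 ± 0.01, Aldh1l1 at 7.40 ± 0.14 and the glutamate transporter Slc1a3 at 8.63 ± 0.05. All 9 measured oligodendrocyte markers passed, with a median of 8.16 at percentile 93.40, including the myelin genes Mbp at 9.16 ± 0.04, Mog at 7.15 ± 0.03, Mag at 8.16 ± 0.08 and Mobp at 9.39 ± 0.01. At the out-of-tissue threshold, 7 of the 10 astrocyte and 6 of the 9 oligodendrocyte markers passed, and Gfap, Aqp4 and Mog did not. Among random lists of genes above background, these medians stood at percentiles 47.60 and 63.24.

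Markers of oligodendrocyte precursors, microglia and vessels depended on the threshold. All 6 precursor markers, all 9 measured microglia markers and 9 of the 10 endothelial and mural cell markers were above background, with medians of 6.51, 6.82 and 6.67. At the out-of-tissue threshold, 1, 3 and 2 of them passed: Pdgfra, the microglial Cx3cr1, C1qb and Csf1r, and the vascular Flt1 and Acta2. Of these, C1qb at 7.62 ± 0.17, Csf1r at 7.61 ± 0.02 and Acta2 at 8.04 ± 0.12 were named after their values were seen. The precursor genes Pdgfra and Cspg4 were at 7.59 ± 0.01 and 6.57 ± 0.06, Gpr17 at 7.04 ± 0.07 and Bmp4 at 6.21 ± 0.19. The microglial genes Cx3cr1, Tmem119, P2ry12 and Aif1 were at 7.83 ± 0.11, 6.58 ± 0.06, 6.71 ± 0.18 and 5.84 ± 0.08. The endothelial genes Flt1, Pecam1, Tek and Cldn5 were at 7.16 ± 0.14, 6.67 ± 0.11, 6.14 ± 0.05 and 6.04 ± 0.12, and Ly6c1 was not above background at 4.37 ± 0.32. Whether any of these transcripts was lower or higher than in whole cortex was not measured here.

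**Figure D3:**
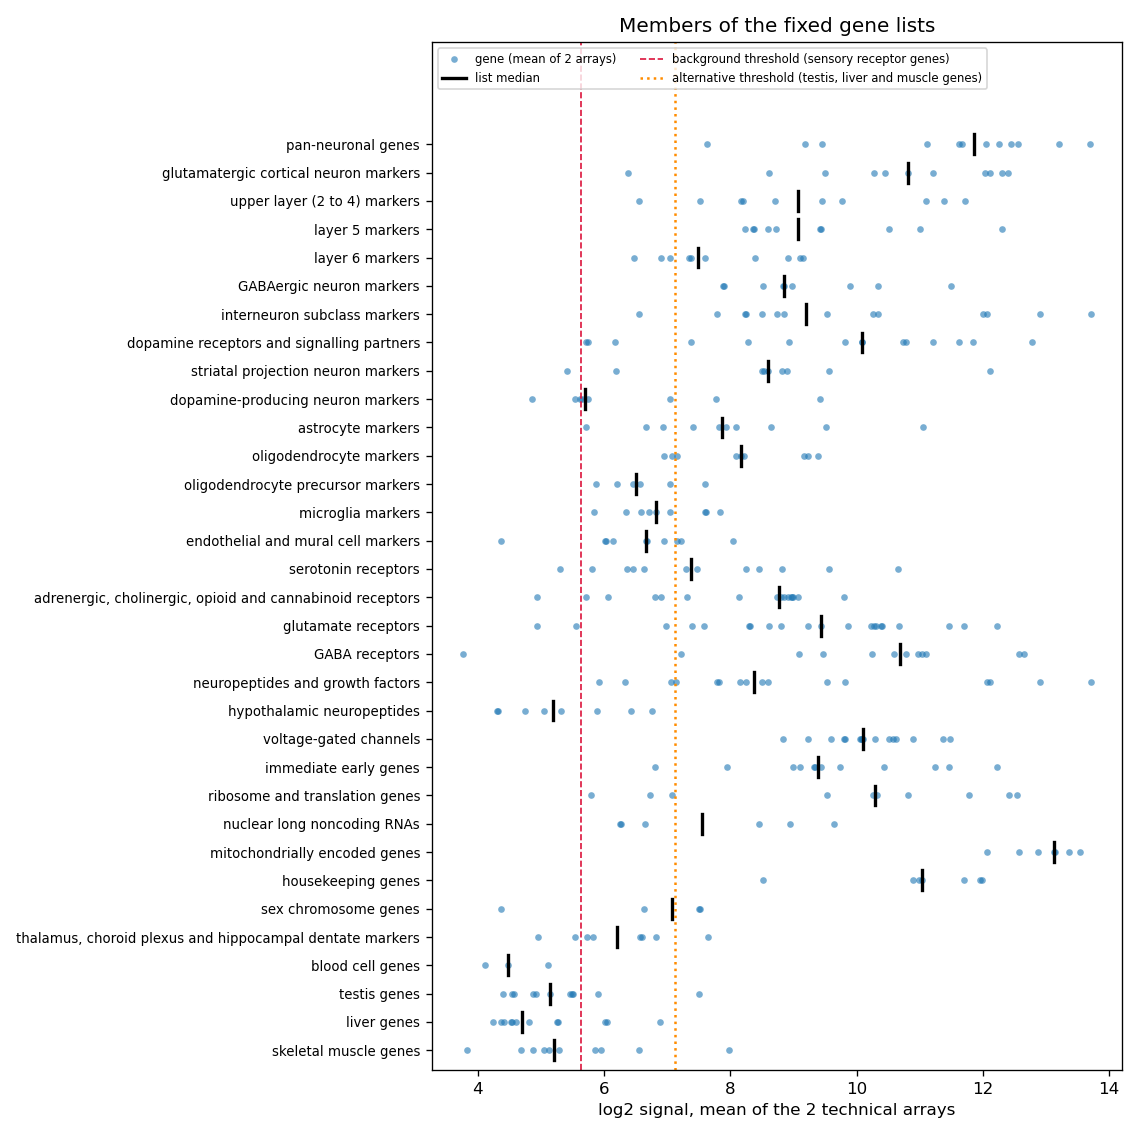
Mean log2 signal over the 2 technical arrays (x axis) of each measured member (points) of the 33 fixed gene lists (rows), with list medians (bars), the mean background threshold from sensory receptor genes (dashed) and the alternative from testis, liver and muscle genes (dotted). Pan-neuronal, glutamatergic, GABAergic and voltage-gated channel lists lie mostly right of both lines, microglia, precursor and vascular lists mostly between them, and blood cell, testis and liver lists mostly left of the dashed line.

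Activity-regulated genes gave signal as a group. All 12 immediate early genes were above background, with a median of 9.39 at percentile 99.95. The transcription factor genes Fos, Fosb and Junb were at 9.11 ± 0.01, 9.44 ± 0.01 and 10.44 ± 0.14, and the synaptic gene Arc at 11.46 ± 0.01. There was no second condition against which to place these levels.

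RNAs that are not translated by cytosolic ribosomes were detected beside those that are. All 7 measured mitochondrially encoded messengers were above background with a median of 13.12, which exceeded all 10000 random lists. ND1, ND2, ND4 and ND5, which encode subunits of respiratory complex I, were at 12.87 ± 0.07, 12.57 ± 0.04, 13.53 ± 0.09 and 13.12 ± 0.06. All 6 measured nuclear long noncoding RNAs were above background, with Malat1 at 9.63 ± 0.17, Neat1 at 6.64 ± 0.09, Meg3 at 6.25 ± 0.06 and Miat at 6.26 ± 0.07, and 3 of them passed the out-of-tissue threshold: Malat1 and, named after their values were seen, Snhg11 at 8.45 ± 0.01 and Rian at 8.94. All 10 ribosome and translation genes passed with a median of 10.29. They included Rps6 at 12.41 ± 0.09, Rplp0 at 7.07 ± 0.07, Rpl22l1 at 5.79 ± 0.06 and Rpl22, the gene tagged in these mice, at 6.73 ± 0.03. At the out-of-tissue threshold 7 of the 10 passed by their means. Rpl22l1 and Rpl22 did not, nor did the Rplp0 mean, which averaged probe sets at 5.80 and 8.33, although the latter did. All 7 measured housekeeping genes passed with a median of 11.04, with Actb at 10.98 ± 0.02, Gapdh at 11.98 ± 0.09, Hprt at 10.89 ± 0.11 and Tbp at 8.52 ± 0.05. Ribosomal protein genes and Gapdh have many processed pseudogenes, so their probe sets can share targets.

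Most genes of other tissues were not above background. Of the measured genes of testis, liver and skeletal muscle, 2 of 11, 3 of 12 and 4 of 10 were above background, at percentiles 6.24, 0.97 and 6.77. Albumin (Alb) was at 4.37 ± 0.08, Apob at 4.60 ± 0.28, the protamine Prm1 at 5.50 ± 0.16, the transition proteins Tnp1 and Tnp2 at 5.49 ± 0.16 and 4.88 ± 0.26, and the myosins Myh1, Myh2 and Myh4 at 4.88 ± 0.13, 5.12 ± 0.10 and 4.69 ± 0.17. The members that passed were Odf1 at 7.50 ± 0.05, Tssk2 at 5.91, Apoa1 at 6.04 ± 0.13, Apoa2 at 6.88 ± 0.30, Cps1 at 6.02 ± 0.01, Acta1 at 7.99 ± 0.13, Ckm at 5.86 ± 0.08, Tnnt3 at 5.96 ± 0.06 and Tnni2 at 6.54 ± 0.04. At the 99th percentile of sensory receptor genes only Odf1, Apoa2 and Acta1 of these passed. The Odf1 value averaged probe sets at 4.98 and 10.02. None of the 3 measured blood cell genes passed, with Ptprc at 4.12 ± 0.20, Cd3e at 5.11 ± 0.38 and S100a8 at 4.47 ± 0.07. Of 8 markers of thalamus, choroid plexus and dentate gyrus, 5 were above background. Tcf7l2 was at 5.83 ± 0.07, Prkcd at 6.60 ± 0.10, Lef1 at 6.57 ± 0.08 and, named after their values were seen, Kl at 6.83 ± 0.23 and Prox1 at 7.64 ± 0.06, of which only Prox1 passed the out-of-tissue threshold. In contrast, Ttr at 5.74 ± 0.19, Folr1 at 5.54 ± 0.22 and Dsp at 4.95 ± 0.04 were not above background on both arrays. Of the 4 measured sex chromosome genes, the Y-linked Kdm5d at 6.63 ± 0.03, Eif2s3y at 7.51 ± 0.11 and Uty at 7.50 ± 0.04 were above background and the X-inactivation transcript Xist at 4.37 was not. Kdm5d did not pass the 99th percentile of sensory receptor genes or the out-of-tissue threshold.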

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

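Signal also lay in probe sets that the report does not use. Of the 9137 probe sets left unnamed by the annotation used here, 2510 (27.47%) exceeded the background threshold on both arrays. Of the 1814 probe sets that name several genes, 981 (54.08%) did, against 60.30% of the named genes and 64.07% of those other than sensory receptor genes. No group held enough samples to look for a sample far from the others, and with 1 group there were no effects to compare.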

How the results depend on the processing

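The choice of background decided more than any other setting. With the out-of-tissue threshold, the number of genes above background was 8541 in place of 13374, and the counts were 2 for dopamine-producing neuron markers, 1 for oligodendrocyte precursor markers, 3 for microglia markers, 2 for endothelial and mural markers, 7 for serotonin receptors, 0 for hypothalamic neuropeptides, 3 for nuclear noncoding RNAs and 1 for thalamus, choroid plexus and dentate markers. With the 99th percentile of sensory receptor genes they were 2 for precursors, 5 for microglia, 4 for endothelial and mural cells, 7 for serotonin receptors, 1 for hypothalamic neuropeptides, 3 for nuclear noncoding RNAs, 2 for thalamus, choroid plexus and dentate, and 1 each for testis, liver and skeletal muscle. Drd2 stood 4.10, 3.61 and 4.93 log2 units over the 99th percentile, the out-of-tissue threshold and the median of all probe sets, against 5.10 in the report. Of 154 named genes, 127 were above background; 36 of these lost that call at the 99th percentile, 49 at the out-of-tissue threshold, 11 at the array median and 1 (Mir669h) with the highest probe set. Calls were gained by Grin2c with the highest probe set, Drd3 with only genes of 1 probe set, Ddc, Drd3 and Grin2c without replicate 1, and Folr1, Slc18a2 and Ttr without replicate 2.

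Testis genes fell to 1 above background when only genes with 1 probe set were used. Without members shared with another list, a setting chosen after seeing the data, the counts were 6 for interneuron subclasses, 5 for striatal markers and 8 for neuropeptides, because fewer genes were counted. Quantile normalization, the highest probe set, the array median and each array alone kept every list count within 1.5 times. The Drd2 signal was 10.74 with quantile normalization, as in the report. No other setting could move it by more than its SD. A threshold does not change a signal, Drd2 has 1 probe set, and each of 2 arrays lies within the SD of their mean. Between arrays, r was 0.9957 and the SD of the difference 0.149 for genes above background, with 0 genes over 1 log2 unit apart, and 0.9953, 0.218 and 38 for named genes. At the 99th percentile threshold, 15 genes in place of 69 differed by more than 0.5 units. Apart from the smaller lists, the cause of these changes was not tested. Low signal limits the calls, since the spread between arrays was larger there. No paired analysis was possible because there is 1 group.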

Other observations

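All tests and gene families in this part were chosen after the data were seen. Gene families were described in the same way as the fixed lists, with which 3 of them share members: Syt1 and Syt6 among the synaptotagmins, Rgs4, Rgs5 and Rgs9 among the regulators of G protein signalling, and Pde10a among the phosphodiesterases. All 17 synaptotagmin genes, 28 of 29 semaphorin and plexin genes and 18 of 21 ephrin and ephrin receptor genes, which guide axons and synapses, were above background, at percentiles 99.85, 99.96 and 99.29 among random lists. Of 32 nuclear genes for subunits of respiratory complex I, 31 passed, and so did 34 of 38 proteasome genes and 17 of 21 genes for the V-type ATPase, which fills synaptic vesicles with protons. The medians of these 3 families exceeded all 10000 random lists. Of 21 regulators of G protein signalling, 16 passed, as did 18 of 24 phosphodiesterase genes and 19 of 23 clustered protocadherin genes, at percentiles 98.47, 86.09 and 72.16. Of 36 Hox genes, which pattern the hindbrain and spinal cord but not the forebrain, 7 passed, at percentile 0.56. The corresponding counts were 19 of 49 keratins, 12 of 37 interleukins and 5 of 41 beta-defensins (Defb4, Defb29, Defb35, Defb36 and Defb47), at percentiles 1.73, 0.06 and 0.00.

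Glial and vascular markers were above background although the tag depends on Cre. Non-specific hybridisation at the rate of the out-of-tissue genes is argued against as the whole cause for astrocyte and oligodendrocyte genes. Of these 19 genes, 100% (exact 95% interval from 82.4 to 100) passed, against 27.3% of 33 out-of-tissue genes (13.3 to 45.5). At the out-of-tissue threshold, which is set from those 33 genes and so fixes their own share, 68.4% (43.4 to 87.4) passed. The rule, written after the counts were known, asked that a majority pass there, and that interval also holds shares short of a majority. The sets were not matched for probe sequence, so cross-hybridisation of single probe sets was not tested. For precursor, microglia and vascular genes, non-specific hybridisation cannot be told apart from expression. Of these 25 genes, 96.0% (79.6 to 99.9) passed, but only 24.0% (9.4 to 45.1) lay over the out-of-tissue threshold. All these intervals treat the chosen genes as independent draws, and they measure neither technical nor animal variation. Co-purified RNA that was not on tagged ribosomes stays open: all 7 measured mitochondrially encoded genes, whose messengers are translated by the mitochondrion's own ribosomes, were above background, but this was known before the explanation was framed and says nothing of the glial transcripts themselves. Co-purified RNA stays open as a source for the neuronal lists as well, since no mock precipitation was analysed here. With 1 group, no biological explanation was tested, such as Cre activity in some glial cells or low expression in the captured neurons.

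The labels used here give no sex for the pooled animals. Xist was not above background on the 1 probe set that names it alone, and 3 of 3 measured Y-linked genes were above, of which Kdm5d did not pass the 99th percentile of sensory receptor genes or the out-of-tissue threshold. The 1 probe set that names Xist together with Tsix was not above background either, so that 0 probe sets naming Xist were. These values, seen before the explanation was framed, are consistent with a pool of male mice only, although Xist is a nuclear RNA and ribosome precipitation may itself lower it. The Y-linked signal by itself does not settle it. The 2 measured X-linked partners, Kdm5c of Kdm5d and Kdm6a of Uty, were also above background. For Kdm5d and Uty, reads of X-linked partner genes by the Y-linked probe sets cannot be told apart from signal of the Y-linked genes. Eif2s3x, the X-linked partner of Eif2s3y, was not measured on a probe set of its own, so this was not tested for Eif2s3y. The design offers no female pool with which to check the Xist probe sets.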
